A study of Rattus norvegicus with 6 samples.

How the data were processed

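RNA was measured in 6 samples of rat astrocytes, 3 after OGD/R and 3 after OGD/R with TGF-β1. Per the labels' protocols, RNA was extracted with TRIzol, selected for poly-A, made into TruSeq V2 libraries and sequenced as paired ends on an Illumina instrument. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes list Bowtie2 2.3.3.1 and Cufflinks 2.2.1 and the builds GRCm38 and mm10, which are mouse builds, while the identifiers in the files are rat Ensembl genes and assembled loci. The rat build, the annotation release, the counting tool and whether strand was used are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart, and no coordinates are given.

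Per the file headers, the authors deposited for each sample a count, a CPM, an FPKM and a TPM value per gene. The deposited counts are whole numbers and were not normalized. The file headers name these units without describing the scaling. By the usual meaning of the names, the authors' CPM values are counts scaled to the library total, their FPKM values are also scaled by gene length, and their TPM values are length-scaled shares. The TPM values summed to almost the same total in every library. Genes outside the listed ones account for 149 to 223 counts per library, by the deposited CPM. Gene lengths derived from the deposited CPM and FPKM did not differ by more than 0.5 bases between files in any row. The tests used the counts, and the other units served for that check. The table has 19350 rows, 17376 with rat Ensembl identifiers and 1974 assembled loci, and 515 rows share a symbol with another row. Of the rows, 13670 have a symbol found in the GRCr8 gene table, which was used only for names and neighbours. Among the 67 named genes, 17 overlap another entry there, so reads may be shared and their values are uncertain: Capns1 with Cox7a1, Col1a1 with Sgca, Timp1 with Syn1, Atf5 with Nup62 and Il4i1, Plk1 with Ern2, and Chst11, Lox, Csf1, Cald1, Flt1, Gadd45a, Hmox1, Ggta1, Insig1, Rbfox3, Mbp and Dtx4 with pseudogenes or unnamed loci. No listed gene was at 0 in all libraries. Of 40 genes used by nearly every cell, 3 had no row under their symbol, 2 had a mean under 1 CPM and 1 more, Hprt1, was under 1 CPM in 5 of 6 libraries, so a low or missing value for a single gene may come from the counting or the annotation.

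Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), libraries were scaled by TMM, and the groups were compared by the quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were derived from the coefficient and its F statistic. Before the data were examined, 25 gene lists were fixed, together with the design and most alternatives. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 24 lists with at least 3 tested genes. Where several rows share a symbol, lists used the row with the highest count. Camera with an estimated correlation and fry were alternatives. The p of fry tests whether a list's genes move, on balance, one way (20 lists called), and its mixed p whether they change in either direction (24 lists), and neither compares a list with other genes. With an estimated correlation, 1 of the 11 called lists held, that of TGF-β target genes.

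Genes were named by a rule fixed in advance. It took the 5 genes raised and the 5 lowered most among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, leaving out features without a symbol. It also took Gfap, Vim, Smad7, Ccn2, Tgfb1, Col1a1, Fn1, Acta2, Aqp4, Slc1a2, Lcn2, C3 and Ncan, and the 2 called members with the smallest p of each list. Some genes that this rule takes are not reported here. Other genes named in the text, such as Myh9, Gpx4, Cox7a1, S100b, Sox9, Aldh1l1, Chst15, Chst3, Has2, Foxc1, Prrx1, Mgp and Hprt1, were chosen after their values were seen.

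The alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a replicate block, each library left out, and stricter thresholds. Summing rows of a symbol and leaving out assembled loci were added after seeing the data. In counts simulated from these libraries for OGD/R + TGF-β1 against OGD/R, with 14005 genes tested, edgeR recovered 88.1% of 67 genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 8 false calls. Only 200 genes, all above 5 CPM, were changed there, against 6477 called in the data. The recovery and the number of false calls therefore do not carry over to the data or to lower genes. Pairs of libraries of the same group differed by more than sampling noise (chi-square per degree of freedom of 3.74 to 5.2), so none was counted as a duplicate. Between groups the value was 34.2 to 41.9. The floor that a count of 0 allows, 3 counts, was 0.157 to 0.219 CPM, and it covers counting error only. Figures were drawn with matplotlib 3.10.9.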

Results

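The series compared rat astrocytes after oxygen-glucose deprivation and reperfusion (OGD/R), a culture model of ischaemic injury, with astrocytes given both OGD/R and transforming growth factor beta 1 (TGF-β1). The sample titles do not say when TGF-β1 was added. Poly-A RNA was sequenced from 3 samples of each group. The labels describe the material as a cell line without naming it, and give neither the dose nor the duration of TGF-β1. No uninjured samples were analysed here, so every value describes TGF-β1 on top of OGD/R. The libraries held 13670142, 19159404 and 16709912 counts in OGD/R and 17137800, 17620512 and 15609422 in OGD/R + TGF-β1. Transcripts named as mitochondrial took 2.69% ± 0.069 of the counts in OGD/R and 2.6% ± 0.026 with TGF-β1 (SD, n = 3). The 10 most abundant genes took 4.63% ± 0.017 and 4.97% ± 0.044 (SD, n = 3). Levels below are TMM-scaled CPM (counts relative to the scaled library total), as mean ± SD of 3 libraries per group, and fold changes are log2 values of TGF-β1 over OGD/R with their standard error (SE).

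The question was which genes TGF-β1 altered in the injured cells, which the labels call astrocytes. Of 24 genes known as targets of TGF-β signalling, 20 were higher with TGF-β1 (camera adjusted p = 5.2e-44), among them Pmepa1, Smad7 and Ccn2 by 3.74-fold to 5.15-fold (SE of the log2 change 0.044 to 0.059, n = 3 per group by an edgeR fit across all genes). Of 29 collagen and matrix genes 18 were higher and 3 lower, with Lox and Thbs2 raised (camera adjusted p = 1.3e-14, adjusted p = 0.14 with an estimated correlation). Of 12 genes in the list of chondroitin sulfate proteoglycans and their synthesis, 5 were higher and 3 lower, with Bgn and Chst11 raised (camera adjusted p = 4.8e-06, adjusted p = 0.064 with an estimated correlation). That list also holds the hyaluronan synthase gene Has2, which rose. Tgfb3, the growth factor receptor gene Fgfr3, the haem-degrading enzyme Hmox1 and the serine-synthesis enzyme Phgdh fell by 1.60 to 1.95 on the log2 scale (SE 0.04 to 0.11). Gfap, the classical astrocyte filament, was near 1 CPM in both groups and did not pass the test. Another 8 genes, from a list of 25 homeostatic astrocyte genes, were under 1 CPM, while 5 of the list had no row and 8 were above 10 CPM. These levels leave open whether the cells are astrocytes. Cells of fibroblast or meningeal type cannot be excluded, so the changes cannot be assigned to astrocytes.

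Of 13982 genes tested, 6477 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 3267 were higher and 3210 lower with TGF-β1. A change of at least 2-fold was seen in 953 of them, 495 higher and 458 lower. The groups did not overlap in 7769 genes (55.6%), where chance gives 10%. The first principal component, with 63.5% of the variance, separated the groups. Scaled by library size alone, 6713 genes were called, 2565 higher and 4148 lower, so that 38.2% of calls were higher in place of 50.4%. The samples are called biological replicates in their titles and duplicates in the series' design, and nothing says that they came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

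The named genes raised most were Ctsw, Rpl8, Lamb3, Fbln2 and Srpx2. Ctsw (ENSRNOG00000027096), a lysosomal protease of lymphocytes, rose from 0.46 ± 0.047 to 40.1 ± 0.89 CPM (log2 6.44, SE 0.1; edgeR adjusted p = 7.06e-11). Lamb3 (ENSRNOG00000006025), a laminin chain of basement membranes, rose from 1.27 ± 0.21 to 74.1 ± 1.1 CPM (log2 5.88, SE 0.087). The matrix gene Fbln2 rose from 1.12 ± 0.47 to 48.7 ± 1.2 CPM (log2 5.47, SE 0.15), and Srpx2 from 0.319 ± 0.17 to 10.4 ± 0.93 CPM (log2 5.01, SE 0.28). Those lowered most were Capns1, Rps19l2, Gjb2, Btc and Dtx4. Gjb2 (ENSRNOG00000008855), a gap junction connexin, fell from 12 ± 1.7 to 1.81 ± 0.64 CPM (log2 -2.74, SE 0.22). The epidermal growth factor family ligand Btc fell from 23 ± 2.6 to 3.78 ± 0.16 CPM (log2 -2.60, SE 0.11), and Dtx4 from 12.3 ± 0.8 to 2.22 ± 0.45 CPM (log2 -2.46, SE 0.16).

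Among these 10 genes, Rpl8, Rps19l2, Capns1 and Dtx4 carry a limit. The ribosomal protein gene Rpl8 (ENSRNOG00000048456) was counted 26, 28 and 28 times in the OGD/R libraries and 2340, 45 and 3308 times with TGF-β1 (log2 6.19, SE 1.3; edgeR adjusted p = 0.00271), and its call was lost with limma-voom (adjusted p = 0.397), in a range of 7.98e-08 to 0.397 over 15 alternatives. Without TGF-β1 replicate 3 its log2 change was 5.45. Rps19l2 is uncertain because ENSRNOG00000048199 and ENSRNOG00000037897 share its symbol. The former, which was called, held 3451, 581 and 184 counts in OGD/R and 85, 157 and 79 with TGF-β1 (log2 -3.86, SE 1; edgeR adjusted p = 0.0108). Its call was lost with limma-voom (adjusted p = 0.183) and when both were summed (log2 -0.11; edgeR adjusted p = 0.473), in a range of 0.00157 to 0.473 over 15 alternatives. Without OGD/R replicate 1 its log2 change was -1.65. Capns1 (ENSRNOG00000045747), a subunit of calpain proteases, fell from 36.6 ± 13 to 1.15 ± 0.33 CPM (log2 -5.00, SE 0.3), and its range overlaps that of Cox7a1 in the GRCr8 gene table, as that of Dtx4 overlaps a pseudogene.

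TGF-β target and feedback genes rose as a list, with 20 of 24 tested members higher and 0 lower (camera adjusted p = 5.2e-44, and adjusted p = 0.0038 with an estimated correlation). Counts adjusted over the list alone were 20 higher and 0 lower. Pmepa1 and Smad7, which dampen TGF-β signalling, rose from 127 ± 8.1 to 656 ± 5 CPM and from 23.7 ± 2 to 110 ± 1.8 CPM (edgeR adjusted p = 1.85e-10 and 1.4e-09). Ccn2, a matricellular protein gene, rose from 171 ± 0.42 to 637 ± 60 CPM (log2 1.90, SE 0.059). Of 16 ligands, receptors and SMADs tested, 6 rose and 6 fell (camera adjusted p = 0.24), and 6 and 8 adjusted over the list alone. Tgfb1 itself rose from 158 ± 2.3 to 366 ± 21 CPM (log2 1.21, SE 0.043), while Tgfb3 fell from 134 ± 2.1 to 34.6 ± 1.2 CPM (log2 -1.95, SE 0.04). Of 9 BMP-responsive genes, 5 rose and 0 fell, and 6 and 1 adjusted over the list alone. Hes1 rose from 7.78 ± 1.5 to 23.7 ± 1.8 CPM and Id3 from 122 ± 8.2 to 193 ± 9.5 CPM. The BMP list was called (camera adjusted p = 0.049, adjusted p = 0.42 with an estimated correlation), in a range of 0.028 to 0.42 over 9 camera alternatives. Its call was lost without OGD/R replicate 2 (camera adjusted p = 0.057) or TGF-β1 replicate 3 (0.072), and with the replicate block (0.053). The fry test, which asks whether the genes move one way on balance and compares them with no others, gave 0.0015.

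**Figure D1:**
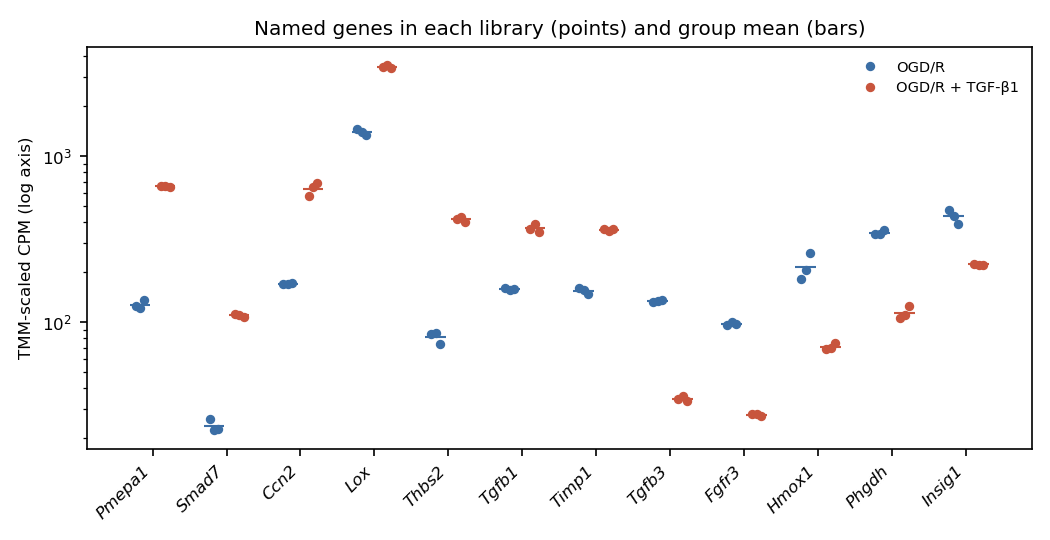
TMM-scaled CPM (log axis) of 12 genes in the 3 OGD/R libraries (blue) and the 3 OGD/R + TGF-β1 libraries (orange-red), with bars at the group means. The groups do not overlap for any of these genes, for example Lox with means of 1390 and 3450 CPM and Fgfr3 with means of 97.5 and 27.8 CPM.

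Collagen and matrix assembly genes rose in 18 and fell in 3 of 29 tested (camera adjusted p = 1.3e-14, adjusted p = 0.14 with an estimated correlation, range 1.1e-18 to 0.14 over 9 camera alternatives), and 18 and 4 adjusted over the list alone. Lox, the enzyme that crosslinks collagen, rose from 1390 ± 54 to 3450 ± 71 CPM (log2 1.31, SE 0.03). Thbs2, a secreted thrombospondin, rose from 81.6 ± 6.9 to 416 ± 14 CPM (log2 2.35, SE 0.058). Fibronectin (Fn1) rose from 792 ± 42 to 1130 ± 34 CPM and Col1a1 from 5180 ± 230 to 6720 ± 350 CPM. Of 9 fibroblast and meningeal markers, described below, 5 rose, among them Col1a1, which is in both lists, and 1, Aldh1a2, fell. That marker list was not called (camera adjusted p = 0.38). A larger share of such cells can therefore not be told apart from a change within the cells. Among 12 genes of the proteoglycan core and synthesis list, 5 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 4.8e-06, adjusted p = 0.064 with an estimated correlation, range 6.8e-08 to 0.064 over 9 camera alternatives). The largest change in this list was in Has2, a hyaluronan synthase gene and not one of chondroitin sulfate. Has2 rose from 0.694 ± 0.25 to 16.6 ± 0.84 CPM (log2 4.54, SE 0.19), and the list was not tested without it. Chst11, a chondroitin sulfotransferase, rose from 28.9 ± 1.2 to 130 ± 5.1 CPM (log2 2.17, SE 0.048), and biglycan (Bgn) from 626 ± 11 to 1150 ± 23 CPM. The sulfotransferase genes Chst15 (log2 -1.54, SE 0.086) and Chst3 (log2 -1.12, SE 0.089) fell, to 7.91 ± 0.28 and 9.19 ± 0.81 CPM. The neural proteoglycan Ncan was near the floor, at 0.11 ± 0.096 and 0.0417 ± 0.036 CPM, and was not tested.

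Of 19 actin cytoskeleton and contractile genes, 11 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 9.5e-04, adjusted p = 0.21 with an estimated correlation, range 1.7e-04 to 0.21 over 9 camera alternatives). The fibronectin receptor chain Itga5 rose from 159 ± 9.5 to 326 ± 3.9 CPM, and the actin-binding protein gene Cald1 from 865 ± 21 to 1340 ± 39 CPM. Acta2, smooth muscle actin, rose from 2.24 ± 0.3 to 4.47 ± 0.59 CPM (log2 0.99, SE 0.19; edgeR adjusted p = 0.00149).

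Genes described in reactive astrocytes moved both ways. Among 13 pan-reactive genes 5 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.044, adjusted p = 0.21 with an estimated correlation). Vimentin (Vim), an intermediate filament, rose from 2710 ± 73 to 4400 ± 62 CPM (log2 0.70, SE 0.024), and the metalloproteinase inhibitor Timp1 from 155 ± 7.1 to 361 ± 4.7 CPM. Lcn2, a secreted siderophore-binding protein gene, fell from 3.38 ± 1.5 to 1.94 ± 0.27 CPM (log2 -0.81, SE 0.3; edgeR adjusted p = 0.0474). That call was lost with limma-voom (adjusted p = 0.0717) and without OGD/R replicate 3 (log2 -0.38, 0.226) or TGF-β1 replicate 1 (0.128), 2 (0.107) or 3 (0.0612), with edgeR, DESeq2 and limma-voom values from 0.0301 to 0.226 over 15 alternatives. The pan-reactive list lost its call without TGF-β1 replicate 2 (camera adjusted p = 0.062), with library size alone (0.052) and with the replicate block (0.065). Its range was 0.032 to 0.21 over 9 camera alternatives (fry 1.5e-04). Gfap was at 0.976 ± 0.34 and 0.737 ± 0.15 CPM (log2 -0.40, SE 0.35; edgeR adjusted p = 0.382).

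All 11 tested genes of the A2-type list changed, 8 higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 9.4e-07, adjusted p = 0.064 with an estimated correlation, range 2.1e-07 to 0.064 over 9 camera alternatives). The lipopolysaccharide co-receptor Cd14 rose from 26.9 ± 1.8 to 130 ± 7.8 CPM, and the prostaglandin synthase Ptgs2 from 23.8 ± 1.9 to 109 ± 4.7 CPM. In the A1-type list 2 rose and 3 fell of 6 tested, also when adjusted over the list alone (camera adjusted p = 0.6). Gbp2, an interferon-induced GTPase, fell from 55.7 ± 1.2 to 27.6 ± 1.8 CPM, and Ggta1 rose from 16.3 ± 0.8 to 31.6 ± 2.2 CPM. The complement gene C3 stayed under the counting floor, at 0.0434 ± 0.038 and 0.0587 ± 0.058 CPM. The difference between the A1-type and A2-type lists was not tested.

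Of 15 homeostatic astrocyte genes tested, 5 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.44). The list's median log2 change was 0.121, its mean -0.1 and the test's direction up. Mfge8, a bridging factor for phagocytosis, rose from 463 ± 15 to 1290 ± 49 CPM (log2 1.48, SE 0.036), and Fgfr3 fell from 97.5 ± 2.2 to 27.8 ± 0.41 CPM (log2 -1.81, SE 0.043). The glutamate transporter Slc1a2 had a mean of 0.0995 ± 0.067 CPM in OGD/R and 0 counts in each TGF-β1 library, which allows up to 0.17 to 0.192 CPM for counting error alone, so a difference was not detectable at this depth. The water channel Aqp4 has no row under that symbol. Low levels of single genes carry a limit, because Myh9 and Gpx4, genes of nearly every cell, were also under 1 CPM.

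**Figure D2:**
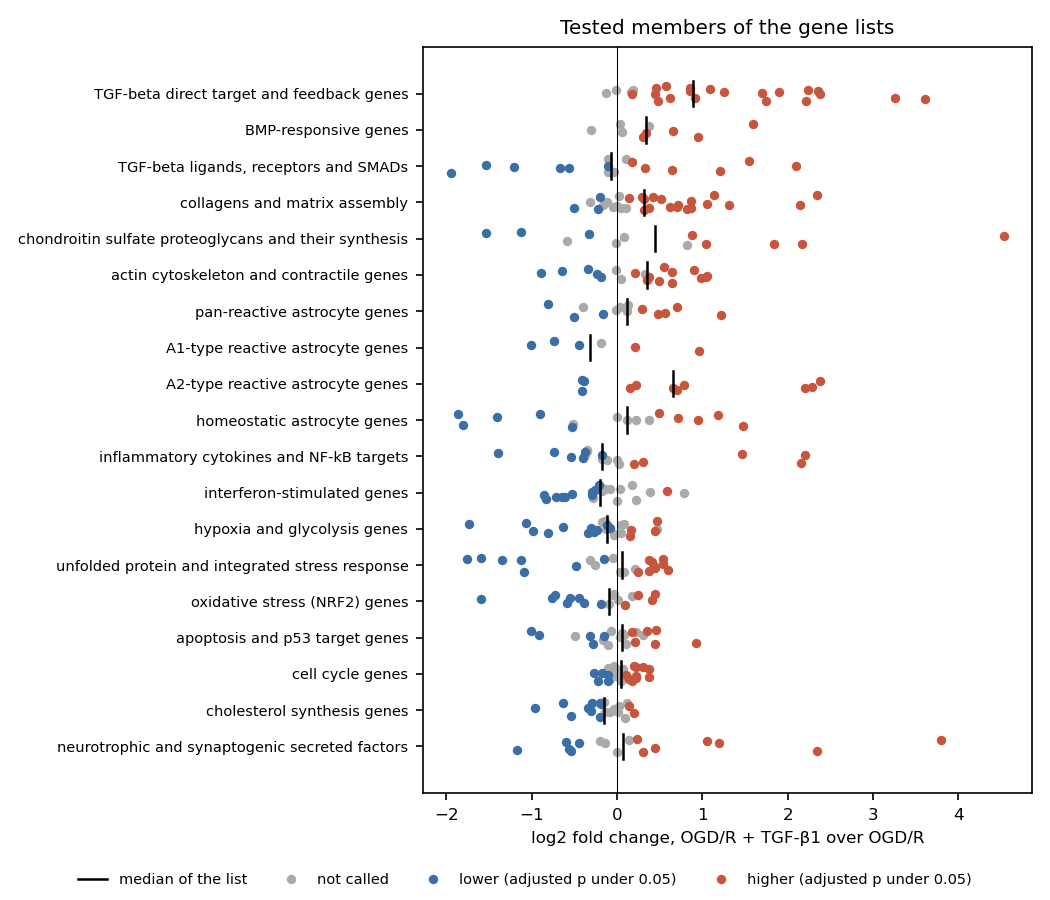
Log2 fold change of TGF-β1 over OGD/R (horizontal axis) for each tested member of 19 gene lists, with genes higher in orange-red, lower in blue, not called in grey and the list median as a black line. TGF-β target genes have a median of 0.893 and 0 members called lower, and unfolded protein and integrated stress response genes lie on both sides of 0.

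Inflammatory cytokine and NF-κB target genes showed no common direction, with 5 higher and 6 lower of 18 tested (camera adjusted p = 0.97), and 5 and 7 adjusted over the list alone. Their median log2 change was -0.176, their mean 0.076 and the test's direction up. Ptgs2 is also a member of this list, and the macrophage growth factor Csf1 fell from 87.4 ± 4.7 to 52.1 ± 1.6 CPM. Interferon-stimulated genes fell as a list, with 1 higher and 10 lower of 22, also when adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.21 with an estimated correlation). The immunoproteasome subunit Psmb9 fell from 35 ± 0.29 to 23 ± 1.2 CPM (log2 -0.61, SE 0.056). With library size alone the interferon list missed the threshold (camera adjusted p = 0.052), in a range of 0.034 to 0.21 over 9 camera alternatives (fry 5.2e-04).

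Oxidative stress genes of the NRF2 group fell, with 4 higher and 8 lower of 17, and 5 and 9 adjusted over the list alone (camera adjusted p = 0.041, adjusted p = 0.38 with an estimated correlation). Hmox1 fell from 215 ± 40 to 71.1 ± 3.1 CPM (log2 -1.60, SE 0.11), and the glutathione synthesis gene Gclc from 291 ± 8.8 to 193 ± 2.7 CPM. Cholesterol synthesis genes also fell, with 2 higher and 9 lower of 19, and 2 and 10 adjusted over the list alone (camera adjusted p = 0.037, adjusted p = 0.74 with an estimated correlation). Insig1, a sterol-regulated gene that restrains the pathway, fell from 433 ± 40 to 223 ± 1.3 CPM (log2 -0.96, SE 0.057). The NRF2 call was lost without TGF-β1 replicate 1 (camera adjusted p = 0.065) or 2 (0.062), in a range of 0.013 to 0.38 over 9 camera alternatives (fry 0.0046). The cholesterol call was lost without OGD/R replicate 1 (camera adjusted p = 0.059) or 2 (0.057), in a range of 1.6e-04 to 0.74 over 9 camera alternatives (fry 0.053).

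Hypoxia and glycolysis genes gave 4 higher and 11 lower of 25, also when adjusted over the list alone, without a call for the list (camera adjusted p = 0.15). Ndrg1, a hypoxia-induced gene, fell from 239 ± 13 to 136 ± 2.7 CPM, and the glycolytic enzyme gene Eno1 rose from 1350 ± 16 to 1840 ± 7.9 CPM. Unfolded protein and integrated stress response genes split, with 9 higher and 7 lower of 22, also when adjusted over the list alone (camera adjusted p = 0.36). Their median log2 change was 0.058, their mean -0.178 and the test's direction down. Phgdh fell from 344 ± 11 to 114 ± 9.4 CPM (log2 -1.60, SE 0.055) and the transcription factor Atf5 from 165 ± 5.2 to 64.6 ± 4.4 CPM (log2 -1.35, SE 0.05).

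Apoptosis and p53 target genes gave 6 higher and 5 lower of 21, and 7 and 5 adjusted over the list alone (camera adjusted p = 0.83). Gadd45a, a stress-induced growth arrest gene, fell from 70.9 ± 2.9 to 35.2 ± 0.91 CPM. This list had a median of 0.058, a mean of -0.007 and the test's direction up. Cell cycle genes gave 10 higher and 5 lower of 29, also when adjusted over the list alone (camera adjusted p = 0.44). The mitotic genes Plk1 and Ccnb1 rose from 195 ± 4.9 to 252 ± 2.7 CPM and from 178 ± 9.6 to 222 ± 5 CPM. Secreted neurotrophic and synaptogenic factors gave 7 higher and 5 lower of 16, also when adjusted over the list alone (camera adjusted p = 0.079, and 0.034 without OGD/R replicate 3, in a range of 0.034 to 0.24 over 9 camera alternatives; fry 1.7e-04). Thbs2, described among the matrix genes, is also a member of this list.

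Markers of other cell types were mostly under 1 CPM or not listed, except in the fibroblast and meningeal list. There 6 of 16 were above 10 CPM, against 8 of 25 homeostatic astrocyte genes. Of 16 microglia and macrophage markers, 9 had no row and 4 were too low to test, while Tmem119 rose from 33.1 ± 2.5 to 134 ± 3.1 CPM and Csf1r from 49.7 ± 3.6 to 106 ± 1.8 CPM. With 3 tested, 2 higher and 0 lower, also when adjusted over the list alone, this list was called (camera adjusted p = 3e-08, adjusted p = 0.064 with an estimated correlation, range 1.8e-08 to 0.064 over 9 camera alternatives). Fibroblast and meningeal markers gave 5 higher and 1 lower of 9, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.38), with Twist1 rising from 10.9 ± 0.99 to 20.2 ± 1.3 CPM and Aldh1a2 falling from 173 ± 4.1 to 123 ± 3.9 CPM. Mgp (log2 1.07, SE 0.22), Foxc1 (log2 0.53, SE 0.068) and Prrx1 (log2 0.33, SE 0.095) also rose. Col1a1 and Col3a1 are members of both this list and the collagen list, and Col3a1, at 1370 ± 95 and 1230 ± 96 CPM, was not called. Endothelial and pericyte markers gave 2 higher and 4 lower of 6 (camera adjusted p = 0.4). Flt1 rose from 174 ± 8.8 to 311 ± 9.6 CPM and Anpep fell from 94.9 ± 1.3 to 49.4 ± 2.3 CPM. Neuron markers gave 2 higher and 4 lower of 7 (camera adjusted p = 0.63), with a median log2 change of -0.168, a mean of 0.071 and the test's direction down. Rbfox3 fell from 6.17 ± 1 to 1.4 ± 0.099 CPM and Dcx rose from 1.7 ± 0.49 to 4.84 ± 0.31 CPM. Oligodendrocyte markers gave 0 higher and 2 lower of 5 (camera adjusted p = 0.38), Cnp falling from 60 ± 2.3 to 47.1 ± 1.2 CPM and Mbp from 0.873 ± 0.15 to 0.18 ± 0.15 CPM. Myrf, the most abundant gene of this list, was at 446 ± 9.5 and 443 ± 27 CPM and was not called. The log2 change of Mbp, on 1, 6 and 2 counts with TGF-β1, moved from -2.23 to -3.13 without TGF-β1 replicate 2. The counts for endothelial, neuron and oligodendrocyte markers were the same when adjusted over the list alone, and 0 of the 12 ependymal and choroid plexus markers could be tested.

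**Figure D3:**
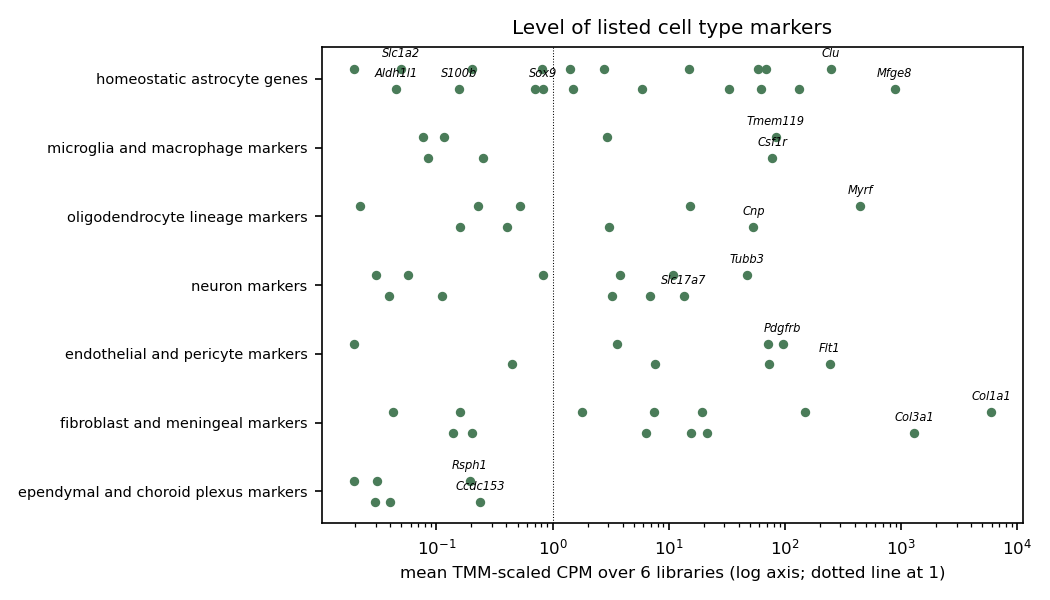
Mean TMM-scaled CPM over 6 libraries (log axis) of each listed marker in 7 lists, with a dotted line at 1. Aldh1l1, Slc1a2, S100b and Sox9 lie under 1 CPM, and Col1a1 is the most abundant marker plotted.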

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

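Summing counts of a symbol (6485 genes called) and leaving out assembled loci (6109) were chosen after seeing the data. The count of changed genes, 6477, stayed within 1.5 times under other scaling, tests and filters (5611 to 6713), and under an adjusted p under 0.01 (4593). Requiring an absolute log2 fold change of at least 1 left 953 genes, 495 higher and 458 lower, by that threshold's own construction. Leaving out each library gave 5481 to 6100 genes, 2833 to 3116 higher and 2648 to 2984 lower. Called lists, 11 with preset-correlation camera, numbered 1 with an estimated correlation and 20 with fry, which tests another question. Under these alternatives none of 943 single-gene values and 240 list values reversed. Of 51 counts of genes, 48 stayed within 1.5 times, and 3, those with the fold change threshold, did not. With library size alone the balance shifted to 2565 higher and 4148 lower. Calls were lost by 8 single-gene values (Rpl8, Rps19l2 and Lcn2) and 22 of the list values, while 11 list values gained one. For these the cause was not tested, except that summing changes what Rps19l2 holds. The replicate block gave 6031 genes and lost the calls of BMP-responsive (0.053) and pan-reactive genes (0.065). Same-numbered libraries correlated at -0.045, 0.018 and -0.039 in their deviations from the group means, and OGD/R replicate 1 correlated best with TGF-β1 replicate 3 (0.032). These values gave no sign of pairing by number. Whether the check could detect shared cultures was not tested, so pairing is not excluded. The planned pseudocount and filter for normalized values were not run, since the files hold counts. Depth limits genes under about 0.157 to 0.219 CPM.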

Other observations

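The terms of the authors' deposited pathway annotation, and the tests named below for copy-named rows, fibroblast transcripts, gene names, dilution and genes of nearly every cell, were chosen after results were seen, as were the check with planted copies and the count of same-symbol partners that the search missed. The genes named in this part were also chosen after their values were seen.

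Ribosome biogenesis genes rose, with 48 higher and 2 lower of 72 tested (camera adjusted p = 6.9e-04 over 202 terms, adjusted p = 0.84 with an estimated correlation). Nop56, a component of the particles that modify ribosomal RNA, had a log2 change of 0.41 (SE 0.034), and the nucleolar methyltransferase Fbl of 0.34 (SE 0.036). Lysosome genes fell, with 19 higher and 54 lower of 101 (camera adjusted p = 0.034, adjusted p = 0.84 with an estimated correlation), among them the membrane protein Lamp1 (log2 -0.32, SE 0.026) and the glucosidase Gaa (log2 -0.58, SE 0.045). Glycosaminoglycan degradation genes gave 0 higher and 11 lower of 13 (camera adjusted p = 0.033, adjusted p = 0.84 with an estimated correlation). Branched-chain amino acid degradation genes gave 1 higher and 22 lower of 41 (camera adjusted p = 0.013, adjusted p = 0.84 with an estimated correlation). Glycine, serine and threonine metabolism genes gave 4 higher and 10 lower of 25 (camera adjusted p = 0.0058, adjusted p = 0.84 with an estimated correlation). p53 signalling genes gave 23 higher and 9 lower of 58 (camera adjusted p = 0.013, adjusted p = 0.84 with an estimated correlation), with Gadd45g at a log2 change of 1.96 (SE 0.062) and Gadd45a at -1.01 (SE 0.051), while the list of apoptosis and p53 target genes fixed in advance was not called (camera adjusted p = 0.83). In all, camera called 6 terms up and 7 down, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05 and fry called 146.

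Grouping the 6 libraries in the other ways into 3 and 3 gave at most 0 genes called by edgeR against 6477 for the real grouping, and 108 to 225 genes at an unadjusted p under 0.05 against 7407. With 1 of 10 splits as large, the splits are too few for a share under 0.05. Each of the other splits mixes the groups, so the difference between the groups adds to the spread within each side. Their low counts are therefore not a measure of noise.

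In 60 rows above 10 CPM, the CPM differed over 10-fold within a group, and 12 of them were called, Rpl8 and Rps19l2 included. A difference in depth is argued against, since CPM is scaled by depth and the library totals differed at most 1.4-fold. The lowest value lay in the shallowest library of its group in 21.1% of cases. A single partner row that takes up the missing reads stays open: it was found for 2 of the rows against 0 to 4 after shuffling and for 39 of 50 planted copies. For Rps19l2 the best partner was its same-symbol row, which was lowest where Rps19l2 was highest. That pair missed the limit (CV of the sum 0.16, limit 0.1). Rows with placeholder names or shared symbols made up 43.3% of the 60 against 2.2% of 9873 other rows (Fisher's exact test, two-sided, p = 1.1e-26), a definition that replaced a wider one in which names ending in l and a number also counted (55% against 7.38%, p = 9.85e-22), so reads divided among several annotated copies may be involved. No biological explanation was tested for these rows, and the calls among them are doubtful as changes in expression.

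Homeostatic astrocyte genes differed in level, 8 of the listed ones above 10 CPM, with Mfge8 at 877 and Clu at 249 CPM, and 8 under 1 CPM, which argues against a mismatch of names for those low ones, while Col1a1 was at 5180 and 6720 CPM. Cells of fibroblast or meningeal type may be present and cannot be excluded: Dcn, Lum, Ogn and Dpt summed to at most 0.805 CPM, but Lum and Dpt have no row, and Aldh1a2, Twist1, Foxc1 and Prrx1 were above 10 CPM, of which Aldh1a2 was lower and the other 3 higher with TGF-β1. Low values of single genes are a weak guide here, because 5 of 40 genes of nearly every cell (12.5%) had no row or a mean under 1 CPM. Gapdh, Fth1, Myh9 and Gpx4 were among them, and the number was 6 (15%) with Hprt1, which was under 1 CPM in 5 of 6 libraries. The genes just named except Hprt1 were also in the lists fixed in advance. Because the 40 were chosen after results were seen, this share may be too high. Of the 25 homeostatic genes, 5 had no row and 8 were under 1 CPM, a larger share than among the 40. That difference in share was not tested, and whether the cells are astrocytes stays open. Dilution of astrocytes by other cells cannot be told apart either, since the 5 homeostatic genes that rose and the 5 that fell bear on differences between groups, and an equal dilution leaves those untouched. The checks for fibroblast or meningeal cells and for dilution did not decide, and no other biological explanation was tested. The series names no other cell type.

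Asns, Phgdh, Psat1 and Atf5, genes known as targets of the transcription factor ATF4, fell by at least 1.09 on the log2 scale. TMM scaling is argued against by its size: without it the median gene shifted by -0.063, so that TMM had made these decreases smaller, and the smallest of the 4 was then -1.15. A lower ATF4 programme stays open as a hypothesis: 13 aminoacyl-tRNA synthetase genes (2 higher, 8 lower) had a median of -0.21 (SE 0.14) and 8 amino acid transporters (2 higher, 4 lower) of -0.23 (SE 0.18), both past the bound of -0.2 set in advance but by less than their SE. The other 7 serine, proline and one-carbon genes (1 higher, 5 lower) had a median of -0.42 (SE 0.27), between the bounds set in advance, and camera called them and the synthetases lower (adjusted p = 0.01 for each, adjusted p = 0.57 with an estimated correlation for each) but not the transporters (0.96). Atf3 (log2 -1.13, SE 0.13) and Ddit3 (log2 -0.48, SE 0.11) also fell, while Atf4 (log2 0.03, SE 0.09), Trib3 and Chac1 did not pass the edgeR test, and an effect of TGF-β1, the difference the design names, by another route stays open and was not tested.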
